A study of Homo sapiens with 84 samples.

How the data were processed

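Expression was measured in 84 cores of lung tissue, 35 from 6 lungs of healthy donors (control) and 49 from 10 lungs with idiopathic pulmonary fibrosis (IPF). Per the labels, lungs were inflated and frozen, cores were drilled from slices, and RNA libraries were made with AmpliSeq, which amplifies a short stretch of each gene, and sequenced on Ion Proton. The FPKM values (fragments scaled to transcript length and to mapped fragments) were made by the authors and used as deposited. Their header is that of a Cufflinks gene tracking table, and the processing notes name TopHat, Bowtie2, Cufflinks 2.2.1 and hg19. Division by transcript length leaves levels of different genes in amplicon data not comparable, so differences in level were tested only within a gene or list score. The FPKM cut-offs, and the share of the FPKM total held by loci under 300 bp, did use levels across genes. That share is therefore not a share of molecules. Read counts were not analysed here. Coordinates are those of the file (hg19).

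The lung of each core was taken from the number before the point in its title, which is a reading of the labels and not stated in them. It was checked in the data without naming a core. Of 84 cores, 75 had their highest correlation with a core of the same number, against a mean of 9.08 and at most 20 when the numbers were shuffled within disease state. The median r was 0.963 between cores of a lung and 0.932 between cores of other lungs of the same state. Fibrosis grades of cores were not analysed here.

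The table held 25276 rows. For 554 symbols with several rows, the row with the highest mean was kept. XIST, TSIX and 158 rows on the Y chromosome were left out, which left 23521 symbols. A gene was kept at a value of at least 1 FPKM in at least 17 cores, which kept 14834 genes, and values entered the tests as log2(FPKM + 1). Relative depth came from 2225 sparse genes, whose values rise in whole-read steps. Of the ratios between values of a pair of cores, 90.1% lay within 0.01 (log2) of a ratio of whole numbers, against 19.2% by chance. Depth ranged from 0.164 to 2.11 of the median core, and 7 cores lay under 0.5. Depth in reads is unknown, so a counting error per gene could not be given.

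The lung was the replicate for disease state. Lung means of IPF and control were compared with limma 3.58.1 (R 4.3.3) with a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg at 0.05. Each of 37 gene lists was scored as the mean log2(FPKM + 1) of its kept members, and scores were compared by exact permutation of the 16 lungs. Of 491 list symbols, 449 were kept, and the rest were not analysed here. Camera, with a preset correlation of 0.01 and with an estimated correlation, tested each list against other genes, and fry tested each list against no change. Spread within a lung was the SD between its cores, tested by exact permutation for the median gene and by limma per gene on the log2 SD, with 0.05 added. The relation to the matrix score, the mean of the 20 kept matrix genes, was fitted with limma with the lung as a block, without the members of that list, and set beside 100 shuffles of the score within lungs. Lung-centred list scores, computed without genes that are also in the matrix list, were correlated with it by Pearson r and Spearman rho, with 100000 permutations of cores within lungs. Differences in r between states were tested with 10000 permutations of disease state over lungs. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the other steps.

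Genes were named by a rule. For disease, these were the 12 largest and 12 smallest log2 differences among genes past the threshold with a mean of at least 5 FPKM in the higher state, and up to 4 members per list with the smallest p. For spread, they were the 6 with the smallest p in each direction. For the matrix score in IPF lungs, they were the 10 largest slopes in each direction past the threshold at a mean of at least 5 FPKM. Immunoglobulin and T cell receptor segments, HLA, XIST and Y-linked genes were not named. The results of 2 list members that the rule picks are not reported here.

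Tested on simulated data, with 200 of 14834 genes changed, the disease comparison recovered 80% of genes at a log2 difference of 1 and 95% at 2, with 3.31% of calls false. The test of spread recovered 30% at a log2 ratio of 1 and 100% at 2, with 4.41% false. The matrix score fit recovered 68% of slopes of 0.5 and 98% of slopes of 1 in IPF cores, and 18% and 74% in control cores. False shares there were 6.74% and 5.15%, above the 5% aimed at. Changed genes were drawn from those with a mean log2(FPKM + 1) above that of 5 FPKM, so genes near the floor were not tried. Noise was independent between genes, so correlation between genes was not simulated. The spread simulation gave a gene the same SD in every lung of a state. Recovery and false shares in the real values may therefore differ.

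Alternatives covered pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, scaling to the same total or to the median, quantile normalization, medians over cores, no trend, robust moderation, random effects of the lung (limma duplicateCorrelation, with a correlation of 0.405, and nlme 3.1.168), cores without regard to lung, each lung left out, and the control lungs of each title style alone. For list scores, z scores were tried, and for spread, draws of 4 cores per lung and the median absolute deviation. For the matrix score, the alternatives were the type 1 score with its sign turned, a score of COL1A1, COL1A2 and COL3A1, and ranks. The share of short loci as a covariate, leaving out loci under 300 bp, scaling to the same total without them, and leaving out the 7 shallow cores were chosen after the data were seen.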

Results

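Gene expression was measured in 84 cores of frozen human lung. Of these, 35 cores came from 6 lungs of healthy donors, called control lungs, and 49 came from 10 lungs removed at transplantation for idiopathic pulmonary fibrosis (IPF), a disease in which scar tissue takes the place of alveoli. A control lung gave 5 or 6 cores and an IPF lung 4 to 6. The study graded the fibrosis of each region by imaging, but the grade of each core was not analysed here, so the comparisons were IPF against control lungs, the spread between cores of a lung, and the relation of genes to a matrix gene score within lungs. The deposited values were FPKM from amplicon libraries. The steps between the values of sparse genes gave the relative depth of each core, which ran from 0.164 to 2.11 times the median, and the depth in reads remained unknown. Relative depth averaged 0.996 ± 0.128 in control and 0.941 ± 0.135 in IPF lungs (SD, n = 6 and 10 lungs, exact permutation p = 0.426, two-sided). Levels below are means ± SD over lungs in FPKM, control (n = 6) first and IPF (n = 10) second, and differences are IPF minus control on the log2 scale. The gene lists and the rule for naming genes were fixed before the data were examined.

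Loci shorter than 300 bp, mainly small RNA genes, held 62.3% to 94.5% of the FPKM total of a core. Their share was 79.7% ± 8.56 in control and 76.8% ± 4.94 in IPF lungs (SD, n = 6 and 10, exact permutation p = 0.400, two-sided). The FPKM total of all other loci was 748924 ± 104691 in control and 842562 ± 72393 in IPF lungs (SD, n = 6 and 10, exact permutation p = 0.0461). Among control lungs, the 3 with 4-digit numbers in their titles had shares of 80.5% to 91.1%, and the other 3 had shares of 69.7% to 74.5%.

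**Figure D1:**
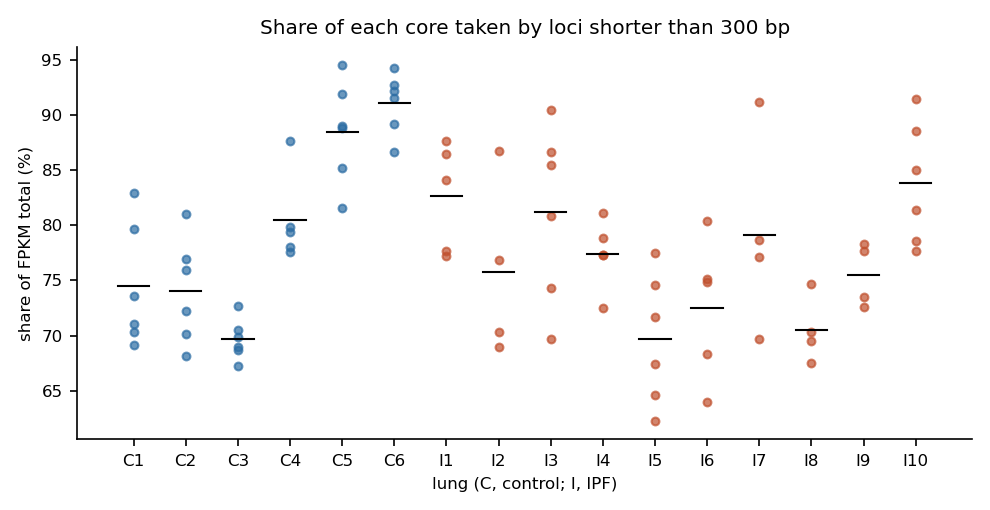
Percent of each core's FPKM total held by loci shorter than 300 bp (vertical axis, not from 0), with each point a core, each black line a lung mean, control lungs C1 to C6 and IPF lungs I1 to I10. Cores ran from 62.3% to 94.5%, and the control lungs averaged 79.7% against 76.8% in IPF lungs.

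The comparison of IPF with control lungs asked which genes differ in advanced disease. Genes of scar matrix rose most. COL1A1, which encodes the main chain of type I collagen (hg19 chromosome 17, 48261456 to 48279000), rose from 32.2 ± 17.5 to 573 ± 361 FPKM, a log2 difference of 3.90 ± 0.46 (SE). THY1, a fibroblast surface protein (chromosome 11, 119288654 to 119294246), rose from 6.27 ± 4.39 to 86.9 ± 51.4 FPKM. KRT17, a keratin of basal epithelial cells (chromosome 17, 39775691 to 39780882), rose from 53.3 ± 54.5 to 426 ± 279.6 FPKM, and MMP7, a matrix metalloproteinase (chromosome 11, 102391238 to 102401478), rose from 30.3 ± 13.4 to 313 ± 196 FPKM. In the other direction, BTNL9, a butyrophilin-like gene (chromosome 5, 180467224 to 180488523), fell from 101 ± 40.9 to 8.66 ± 6.7 FPKM, and S100A12, a calcium-binding protein of neutrophils and monocytes (chromosome 1, 153346183 to 153348075), fell from 99.3 ± 33.1 to 10.7 ± 4.44 FPKM. All 10 IPF lungs lay beyond all 6 control lungs for these 6 genes.

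Of 14834 genes tested with limma on lung means of log2(FPKM + 1), 1808 passed a Benjamini-Hochberg adjusted p of 0.05, 967 higher and 841 lower in IPF lungs, with 294 higher and 206 lower by at least 2-fold. The 12 genes with the largest rise were, with log2 difference ± SE, COL1A1 (3.90 ± 0.46), THY1 (3.68 ± 0.43), KRT17 (3.59 ± 0.46), IGLL5 (3.46 ± 0.52), COL3A1 (3.28 ± 0.32), CXCL14 (3.17 ± 0.31), MMP7 (3.16 ± 0.31), SFRP2 (3.05 ± 0.36), COMP (3.03 ± 0.51), ISLR (3.03 ± 0.28), CTHRC1 (3.02 ± 0.34) and HBA1 (2.90 ± 0.73). Their limma adjusted p ran from 1.07e-05 for ISLR to 0.0144 for HBA1. The 12 with the largest fall were BTNL9 (-3.62 ± 0.37), S100A12 (-3.12 ± 0.25), DEFA3 (-3.09 ± 0.69), DEFA1 (-3.04 ± 0.66), MT1M (-2.81 ± 0.76), ITLN2 (-2.79 ± 0.40), FCN3 (-2.69 ± 0.51), PF4 (-2.67 ± 0.69), MT1A (-2.67 ± 0.61), F2RL3 (-2.56 ± 0.59), SLCO4A1 (-2.50 ± 0.33) and IL1R2 (-2.44 ± 0.63), with limma adjusted p from 2.69e-06 for S100A12 to 0.0217 for MT1M. FCN3 encodes a ficolin of the lectin complement pathway, PF4 a platelet chemokine, and MT1M and MT1A are metallothioneins that bind zinc and copper. DEFA1 and DEFA3, the α-globin genes HBA1 and HBA2, and IGLL5 with its neighbouring light chain locus have near-identical or overlapping copies, so their single values are uncertain. Every IPF lung lay above every control lung for 185 genes and below for 135, where chance gives 0.025% of genes.

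**Figure D2:**
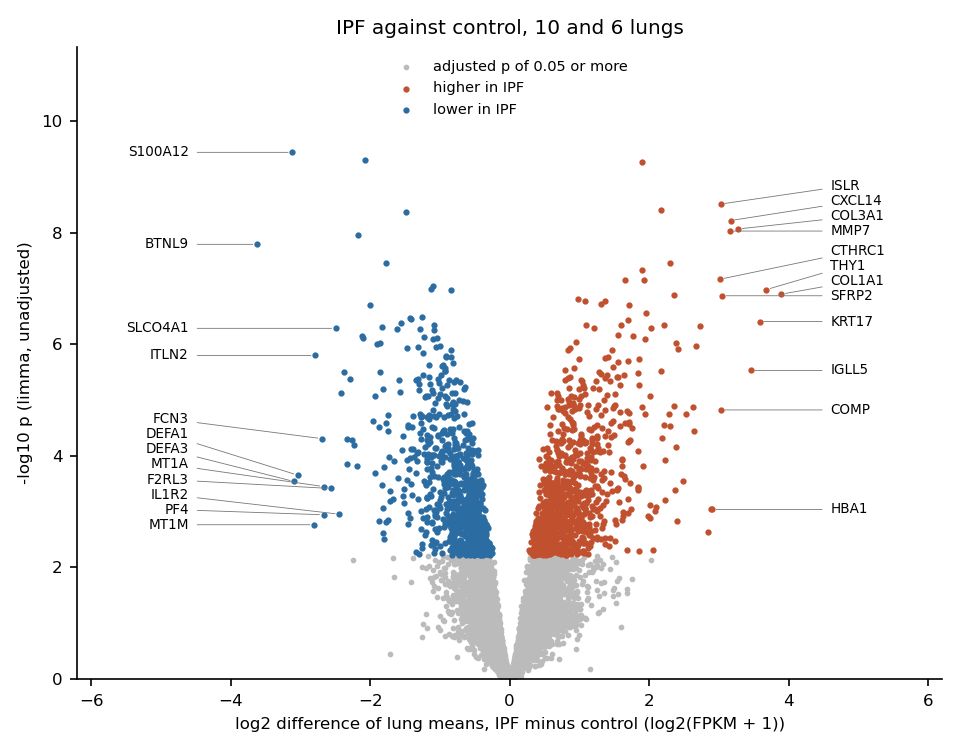
Log2 difference of lung means, IPF minus control (horizontal axis), against −log10 of the unadjusted limma p (vertical axis) for 14834 genes, each point a gene. Genes past an adjusted p of 0.05 are red where higher in IPF (967) and blue where lower (841), and the labels name the 12 largest differences on each side, from COL1A1 at 3.90 to BTNL9 at -3.62.

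Fibrillar collagen and matrix genes rose together. Of 20 measured list members, 17 rose and 0 fell, and 19 rose and 0 fell when adjusted over the list alone. COL3A1 went from 37.3 ± 9.33 to 417 ± 226 FPKM and CTHRC1, a secreted protein of activated fibroblasts, from 2.08 ± 0.747 to 27.7 ± 12.9 FPKM. The list score, the mean log2(FPKM + 1) of the members, was 3.32 ± 0.43 in control and 5.38 ± 0.67 in IPF lungs (difference 2.06, exact permutation test, adjusted p = 0.00154), with 10 of 10 IPF lungs above the control mean. The set test gave adjusted p = 1.6e-20 in camera and adjusted p = 0.0907 with an estimated correlation. Among 14 matrix metalloproteinases and inhibitors, 7 rose and 1 fell, and 10 rose and 1 fell when adjusted over the list alone. MMP11 rose from 0.409 ± 0.442 to 8.62 ± 8.08 FPKM, MMP2 rose from 82.7 ± 32.8 to 226 ± 104 FPKM, and TIMP3, an inhibitor bound to matrix, fell from 252 ± 152 to 84.5 ± 41 FPKM. Their score was 3.64 ± 0.20 in control and 4.57 ± 0.40 in IPF lungs (difference 0.93, exact permutation test, adjusted p = 0.00173), with camera adjusted p = 3.74e-05 (adjusted p = 0.0994 with an estimated correlation). Of 5 measured cartilage and bone genes, 3 rose (COL2A1, COL10A1 and COMP) and 1 fell, MATN3, with a log2 difference of -1.16 ± 0.20. COL10A1, a collagen of hypertrophic cartilage, went from 0.104 ± 0.0614 to 5.48 ± 3.49 FPKM, and 3 rose and 1 fell when adjusted over the list alone. The score of that list differed by 1.24 (exact permutation test, adjusted p = 0.00173), with camera adjusted p = 0.0133 (adjusted p = 0.23 with an estimated correlation).

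Contractile genes did not follow the matrix genes past the threshold. None of 12 myofibroblast and smooth muscle genes passed the limma test, with 0 also when adjusted over the list alone, and 2 had an unadjusted p under 0.05 (ACTG2 and SYNPO2). ACTA2, smooth muscle actin, stood at 533 ± 200.1 against 692 ± 237 FPKM (limma adjusted p = 0.325), and ACTG2 at 109 ± 59.1 against 215 ± 94.5 FPKM (adjusted p = 0.0598). SYNPO2 and CNN1 gave log2 differences of 0.44 and 0.61. The score differed by 0.29 (exact permutation test, adjusted p = 0.369). Of 10 pericyte genes, 1 rose, FAM162B (13.8 ± 4.17 against 31.2 ± 19.9 FPKM), and 0 rose and 0 fell when adjusted over the list alone. The pericyte score differed by 0.092 (exact permutation test, adjusted p = 0.772). CSPG4, RGS5 and HIGD1B of that list gave log2 differences of -0.55, 0.73 and -0.50, none past the threshold. None of 8 mesothelial genes passed the limma test, and 2 had an unadjusted p under 0.05 (LRRN4 and WT1), with WT1 at 0.0737 ± 0.099 against 0.935 ± 0.98 FPKM (adjusted p = 0.0529) and a score difference of 0.044 (exact permutation test, adjusted p = 0.835). LRRN4, UPK3B and ITLN1 of that list gave -0.91, -0.69 and 0.53.

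The epithelium differed by cell type. Of 16 genes of basal cells and of the aberrant basaloid cells described in fibrotic lungs, 11 rose and 0 fell, and 14 rose and 0 fell when adjusted over the list alone. ITGB6, an integrin chain of injured epithelium, rose from 17 ± 5.88 to 32.7 ± 6.61 FPKM, and SOX4 and the basal cell regulator TP63 rose by 0.90 ± 0.17 and 0.83 ± 0.18 on the log2 scale. The basal score was 2.53 ± 0.36 in control and 4.02 ± 0.73 in IPF lungs (difference 1.5, exact permutation test, adjusted p = 0.00205), with camera adjusted p = 4.7e-10 (adjusted p = 0.093 with an estimated correlation). Of 16 secretory and mucous genes, 6 rose and 0 fell, and 10 rose and 0 fell when adjusted over the list alone. The mucin gene MUC5B rose from 3.62 ± 3.68 to 10.4 ± 6.27 FPKM, SCGB3A1 rose from 4335 ± 2255 to 12641 ± 7492 FPKM, and SPDEF and WFDC2 rose by 1.39 and 0.90 on the log2 scale. That score was 6.41 ± 0.23 in control and 7.42 ± 0.77 in IPF lungs (difference 1.01, exact permutation test, adjusted p = 0.0308), with camera adjusted p = 4.25e-05 (adjusted p = 0.291 with an estimated correlation), and passed in 12 of 16 fits with single lungs left out. Of 16 ciliated cell genes, 1 rose, TPPP3 (286 ± 138 against 538 ± 200.2 FPKM), and 1 rose and 0 fell when adjusted over the list alone. TSPAN1, CAPS and CCDC39 gave log2 differences of 1.18, 0.68 and 0.35 without passing. The ciliated score differed by 0.76 (exact permutation test, adjusted p = 0.124), and its set test gave adjusted p = 0.000169 in camera and adjusted p = 0.441 with an estimated correlation.

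Alveolar genes moved the other way, in smaller numbers. Of 13 type 1 genes, 3 fell and 0 rose, and 1 rose and 6 fell when adjusted over the list alone. AGER, the marker of the thin type 1 cell, fell from 621 ± 281 to 194 ± 79.2 FPKM, EMP2 fell from 129.6 ± 48.7 to 56.2 ± 17.3 FPKM, and VEGFA fell from 62.6 ± 28.3 to 33.8 ± 9.94 FPKM. SEMA3B did not pass (limma adjusted p = 0.0613). The type 1 score was 4.95 ± 0.59 in control and 4.43 ± 0.31 in IPF lungs (difference -0.52, exact permutation test, adjusted p = 0.0679), which missed the threshold, and its set test gave adjusted p = 0.0121 in camera and adjusted p = 0.434 with an estimated correlation. The difference rested on the control set, with -0.99 (adjusted p = 0.0185) against controls with title numbers of up to 3 digits and -0.056 (adjusted p = 0.852) against those with 4. Of 14 type 2 genes, 3 fell and 0 rose, and 0 rose and 4 fell when adjusted over the list alone. ABCA3, the lipid transporter of surfactant bodies, fell from 101 ± 38.7 to 51.1 ± 26.7 FPKM, SDR16C5 fell from 23.9 ± 5.95 to 10.5 ± 3.99 FPKM, and PGC fell from 577 ± 342 to 251 ± 169.6 FPKM. Surfactant protein gene SFTPA1 stood at 610.4 ± 134 against 413 ± 176 FPKM (limma adjusted p = 0.0806). The type 2 score was 7.36 ± 0.54 in control and 6.74 ± 0.40 in IPF lungs (difference -0.62, exact permutation test, adjusted p = 0.0488), with camera adjusted p = 0.000266 (adjusted p = 0.369 with an estimated correlation). It passed in only 4 of 16 fits with single lungs left out, with adjusted p up to 0.105.

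By number of genes called, the capillary endothelial list fell most, although the platelet score fell further. Of 19 capillary and general endothelial genes, 13 fell and 0 rose, and 0 rose and 15 fell when adjusted over the list alone. GPIHBP1, which anchors lipoprotein lipase on capillaries, fell from 16.2 ± 7.03 to 3.22 ± 1.85 FPKM, the angiopoietin receptor gene TEK fell from 18.2 ± 4.02 to 6.81 ± 2.08 FPKM, and EPAS1, a hypoxia-inducible factor, fell from 222 ± 58.1 to 77.1 ± 34.5 FPKM. The capillary score was 5.32 ± 0.32 in control and 4.04 ± 0.39 in IPF lungs (difference -1.27, exact permutation test, adjusted p = 0.00154), with 10 of 10 IPF lungs below the control mean, and camera adjusted p = 1.68e-12 (adjusted p = 0.0826 with an estimated correlation). Of 8 genes of peribronchial endothelium and vascular remodelling, 4 rose and 0 fell, and 4 rose and 0 fell when adjusted over the list alone. COL15A1, which is also in the matrix list, rose from 2.65 ± 2.43 to 9.81 ± 3.34 FPKM, and ZNF385D and VWA1 rose by 0.52 and 0.59 on the log2 scale. POSTN, also a matrix gene, rose from 13.9 ± 8.31 to 67 ± 44.2 FPKM. The peribronchial score differed by 0.64 (exact permutation test, adjusted p = 0.00501), with camera adjusted p = 0.00989 (adjusted p = 0.291 with an estimated correlation). COL15A1 and POSTN differed by 1.69 and 2.21 on the log2 scale, against 0.42 for the median member. Much of the score difference therefore repeats the matrix result, and the score without these genes was not compared between states. Among 5 lymphatic genes, LYVE1 fell from 36.5 ± 18.1 to 13.9 ± 8.73 FPKM, none rose, and CCL21 stood at 80.8 ± 77.2 against 162 ± 88 FPKM (limma adjusted p = 0.0592). FLT4 and TFF3 gave log2 differences of -0.47 and 0.96, 2 rose and 2 fell when adjusted over the list alone, and the lymphatic score differed by 0.028 (exact permutation test, adjusted p = 0.905).

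B cell genes and the list of lymphoid follicle chemokines rose. Of 17 B cell and plasma cell genes, 15 rose and 0 fell, and 16 rose and 0 fell when adjusted over the list alone. MZB1, a plasma cell chaperone, rose from 15.6 ± 12.9 to 99.8 ± 65.8 FPKM, the B cell receptor gene CD79A rose from 8.14 ± 5.06 to 48.4 ± 26.2 FPKM, and CD27 and POU2AF1 rose by 1.95 and 1.90 on the log2 scale. The score was 1.57 ± 0.36 in control and 3.0 ± 0.59 in IPF lungs (difference 1.43, exact permutation test, adjusted p = 0.00154), with camera adjusted p = 8.59e-13 (adjusted p = 0.0994 with an estimated correlation). Of 9 genes in the list of follicle chemokines and cytokines, 7 rose and 0 fell, and 9 rose and 0 fell when adjusted over the list alone. Whether each member is particular to follicles was not tested. CXCL13, which draws B cells into follicles and is also in the B cell list, rose from 3.05 ± 3.3 to 28.2 ± 32 FPKM. CXCL12 rose from 78.2 ± 41.7 to 272 ± 102 FPKM, and CXCL14 and LTB rose by 3.17 and 1.51. Their score was 2.85 ± 0.61 in control and 4.43 ± 0.38 in IPF lungs (difference 1.57, exact permutation test, adjusted p = 0.00154), with camera adjusted p = 4.21e-08 (adjusted p = 0.0826 with an estimated correlation). Of 18 T cell and natural killer cell genes, 8 rose and 0 fell, and 9 rose and 1 fell when adjusted over the list alone. CD4 rose from 22 ± 8.63 to 52.2 ± 20.6 FPKM, CD3D rose from 24.4 ± 24.4 to 47.8 ± 14.9 FPKM, and IL2RG and CD5 rose by 0.99 and 1.00. The T cell score differed by 0.66 (exact permutation test, adjusted p = 0.0627), with 10 of 10 IPF lungs above the control mean but 0 above all control lungs. It differed by 0.28 (adjusted p = 0.425) against controls with title numbers of up to 3 digits and 1.04 (adjusted p = 0.0304) against those with 4, and its set test gave adjusted p = 8.99e-05 in camera and adjusted p = 0.395 with an estimated correlation. Of 9 dendritic cell genes, 2 rose, CCR7 (1.2 ± 0.792 against 3.63 ± 1.92 FPKM) and XCR1 (0.287 ± 0.238 against 0.879 ± 0.444 FPKM), and 3 rose and 1 fell when adjusted over the list alone. CLEC4C and LAMP3 gave log2 differences of 0.57 and -0.86. The dendritic score differed by 0.49 (exact permutation test, adjusted p = 0.092), with camera adjusted p = 0.0112 (adjusted p = 0.415 with an estimated correlation).

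Myeloid and blood cell genes moved in opposite directions. Of 14 genes of SPP1 and monocyte-derived macrophages, 5 rose and 1 fell (FABP5, 288 ± 93.7 against 182 ± 38.6 FPKM), and 8 rose and 1 fell when adjusted over the list alone. SPP1 (osteopontin) rose from 8.58 ± 5.11 to 76.3 ± 65.2 FPKM, CCL18 rose from 299.9 ± 275 to 1013 ± 301 FPKM, TREM2 rose from 54.1 ± 12.8 to 165 ± 60.9 FPKM, and GPNMB rose by 1.08 on the log2 scale. The score was 5.33 ± 0.41 in control and 6.28 ± 0.32 in IPF lungs (difference 0.95, exact permutation test, adjusted p = 0.00231), with camera adjusted p = 0.000264 (adjusted p = 0.093 with an estimated correlation). Of 13 alveolar macrophage genes, 1 rose, MSR1 (6.45 ± 3.53 against 12 ± 4.24 FPKM), 5 rose and 0 fell when adjusted over the list alone, and the score differed by 0.42 (exact permutation test, adjusted p = 0.092), with camera adjusted p = 0.0133 (adjusted p = 0.434 with an estimated correlation). INHBA, APOC1 and C1QA of that list gave log2 differences of 1.07, 0.72 and 0.70. Of 15 neutrophil and classical monocyte genes, 9 fell and 0 rose, and 0 rose and 12 fell when adjusted over the list alone. S100A8 fell from 234 ± 83.6 to 50.4 ± 17.1 FPKM, and the interleukin 8 receptor genes CXCR1 and CXCR2 fell by 1.00 and 0.77 on the log2 scale. The neutrophil score was 4.41 ± 0.50 in control and 3.25 ± 0.16 in IPF lungs (difference -1.16, exact permutation test, adjusted p = 0.00154), with camera adjusted p = 4.7e-10 (adjusted p = 0.0826 with an estimated correlation).

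Of 8 platelet genes, 7 fell and 0 rose, and 0 rose and 7 fell when adjusted over the list alone. TUBB1, the platelet tubulin, fell from 7.14 ± 4.57 to 0.965 ± 0.707 FPKM, ITGA2B fell from 5.5 ± 3.56 to 0.787 ± 0.552 FPKM, CLEC1B fell from 9.73 ± 6.37 to 0.817 ± 0.777 FPKM, and NRGN fell by 1.30 on the log2 scale. The platelet score was 3.59 ± 1.31 in control and 1.89 ± 0.43 in IPF lungs (difference -1.70, exact permutation test, adjusted p = 0.00817), with camera adjusted p = 1.19e-06 (adjusted p = 0.15 with an estimated correlation). Only 1 of 10 IPF lungs lay below all controls, since 1 control lung scored 1.25. Of 7 erythroid genes, 3 rose and 0 fell, and 3 rose and 0 fell when adjusted over the list alone. These were the globin genes HBA1, HBA2 and HBB. HBB went from 752 ± 854 to 4878 ± 6633 FPKM, and ALAS2 stood at 0.454 ± 0.556 against 2.3 ± 3.13 FPKM (limma adjusted p = 0.193). The erythroid score was 3.72 ± 1.12 in control and 5.25 ± 0.98 in IPF lungs (difference 1.52, exact permutation test, adjusted p = 0.0308), with camera adjusted p = 0.00446 (adjusted p = 0.403 with an estimated correlation), and passed in 12 of 16 fits with single lungs left out. It differed by 2.31 (adjusted p = 0.0185) against controls with title numbers of up to 3 digits and 0.74 (adjusted p = 0.335) against those with 4. Of 10 mast cell genes, 2 rose (HDC and SLC18A2) and 1 fell (GATA2, 30.5 ± 9.69 against 12.8 ± 4.31 FPKM), and 6 rose and 1 fell when adjusted over the list alone. HDC, which makes histamine, rose from 1.22 ± 0.788 to 3.92 ± 1.75 FPKM, and MS4A2 gave a log2 difference of 0.77. The mast cell score differed by 0.60 (exact permutation test, adjusted p = 0.0627), with camera adjusted p = 0.0398 (adjusted p = 0.434 with an estimated correlation). That score differed by 0.25 (exact permutation test, adjusted p = 0.556) against controls with title numbers of up to 3 digits and 0.96 (adjusted p = 0.0259) against those with 4.

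**Figure D3:**
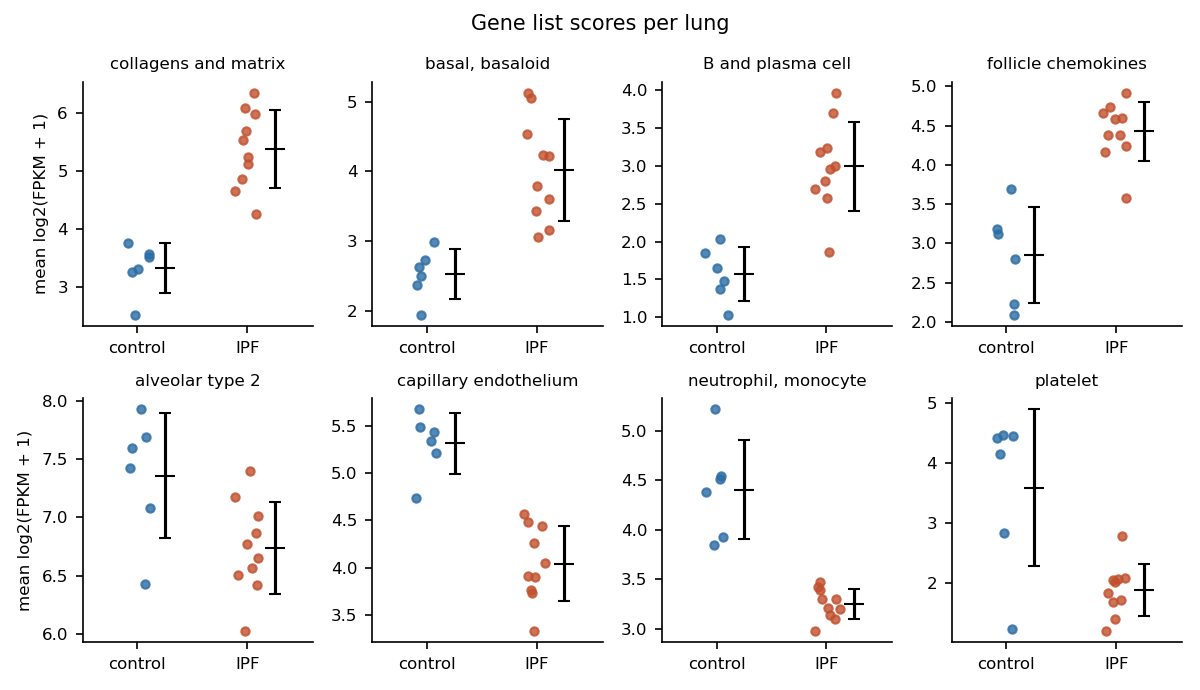
Mean log2(FPKM + 1) of 8 gene lists (vertical axes, which do not start at 0) in 6 control and 10 IPF lungs, each point a lung, with the mean and SD beside the points. The matrix score stood at 5.38 ± 0.67 in IPF against 3.32 ± 0.43 in control lungs, and the platelet score at 1.89 ± 0.43 against 3.59 ± 1.31.

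Stress and pathway lists were mixed. Of 12 proliferation genes, 6 rose and 0 fell, and 11 rose and 0 fell when adjusted over the list alone. TYMS, a thymidylate synthase needed for DNA synthesis, rose from 5.37 ± 2.13 to 15.2 ± 5.17 FPKM, and CCNB2, BIRC5 and TOP2A rose by 0.84, 0.83 and 0.50. Their score differed by 0.58 (exact permutation test, adjusted p = 0.00378), with camera adjusted p = 2.47e-06 (adjusted p = 0.206 with an estimated correlation). Of 13 senescence and p53 target genes, 3 rose (GDF15, IGFBP7 and CDKN1A) and 0 fell, and 5 rose and 0 fell when adjusted over the list alone. GDF15 rose from 50.8 ± 44.8 to 171 ± 133 FPKM, IGFBP7 rose by 0.82, CDKN1A, the p21 cell cycle inhibitor, rose from 108 ± 37.9 to 175 ± 59.5 FPKM, and MDM2 gave a log2 difference of 0.42. The senescence score was 4.45 ± 0.14 in control and 5.03 ± 0.20 in IPF lungs (difference 0.58, exact permutation test, adjusted p = 0.00154), with camera adjusted p = 0.000247 (adjusted p = 0.0621 with an estimated correlation). Of 13 hypoxia and glycolysis genes, 3 fell (BNIP3, ADM and NDRG1) and 0 rose, and 1 rose and 5 fell when adjusted over the list alone. BNIP3 fell from 48.7 ± 13.5 to 26.8 ± 4.56 FPKM, ADM fell from 57.6 ± 20 to 28.3 ± 18.2 FPKM, NDRG1 fell by 0.77, and PFKFB3 gave a log2 difference of -0.57. Their score differed by -0.23 (exact permutation test, adjusted p = 0.0495), and passed in only 4 of 16 fits with single lungs left out (adjusted p up to 0.116). The list was not called by camera, with camera adjusted p = 0.0703 (adjusted p = 0.291 with an estimated correlation). Of 15 immediate early genes, EGR2 and EGR3 rose, by 1.29 and 1.01, and 3 rose and 0 fell when adjusted over the list alone. IER3 and ATF3 of that list gave differences of 1.00 and 0.88, and the score differed by 0.50 (exact permutation test, adjusted p = 0.204), with camera adjusted p = 0.0201 (adjusted p = 0.576 with an estimated correlation).

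Of 18 genes of the transforming growth factor β pathway, 4 rose and 3 fell, and 6 rose and 4 fell when adjusted over the list alone. LTBP2 rose from 5.75 ± 2.45 to 20 ± 9.02 FPKM, the BMP antagonist gene GREM1 rose from 0.147 ± 0.147 to 1.85 ± 1.04 FPKM, and ACVRL1 and SMAD6 fell by 1.19 and 1.19 on the log2 scale. The others were TGFB3 and BMP4, which rose, and ID1, which fell. The score differed by 0.16 (exact permutation test, adjusted p = 0.428). Of 21 Wnt pathway genes, 5 rose and 3 fell, and 5 rose and 4 fell when adjusted over the list alone. SFRP2 and SFRP4, secreted Wnt modulators, rose by 3.05 and 2.52, WNT10A rose by 1.01, and the receptor gene FZD5 fell from 12.7 ± 2.04 to 5.27 ± 1.18 FPKM. FRZB and LEF1 also rose, and NKD1 and WNT3A also fell. The median member differed by -0.042 and the score by 0.14 (exact permutation test, adjusted p = 0.466). Of 18 acute inflammation and ischaemia genes, PTGS2 and SELE rose by 1.00 and 1.17, and NFKBIA fell from 309.8 ± 73.5 to 149 ± 50.4 FPKM. CXCL1 of that list gave 1.13, 2 rose and 1 fell when adjusted over the list alone, and the score differed by 0.21 (exact permutation test, adjusted p = 0.594). Of 13 unfolded protein response genes, CHAC1 and TRIB3 fell by 0.84 and 1.08, PDIA4 and ASNS gave 0.37 and -0.62, 0 rose and 2 fell when adjusted over the list alone, and the score differed by -0.12 (exact permutation test, adjusted p = 0.523).

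None of 16 interferon response genes passed the limma test, and 1 had an unadjusted p under 0.05. OAS1, OAS2 and OAS3, which make activators of RNase L, gave log2 differences of 0.60, 0.62 and 0.58, and the score differed by 0.33 (exact permutation test, adjusted p = 0.385), with camera adjusted p = 0.0398 (adjusted p = 0.689 with an estimated correlation). None of 10 heat shock genes passed either, and 1 had an unadjusted p under 0.05 (HSPB1), with HSPB1 at 477 ± 90 against 629 ± 152 FPKM, HSPH1 at 0.36, HSPA1A and HSPA1B, which are near-identical copies, at 0.29 and 0.20, and a score difference of 0.14 (exact permutation test, adjusted p = 0.385). Adjusted over the list alone, 0 genes of either list passed. Against controls with title numbers of up to 3 digits, the interferon score differed by -0.23 (exact permutation test, adjusted p = 0.562). The heat shock score differed by -0.12 there (adjusted p = 0.352). Against those with 4 digits, the scores differed by 0.90 (adjusted p = 0.0185) and 0.41 (adjusted p = 0.0304), so both results rested on the control set. Of 4 adipocyte genes, LPL, lipoprotein lipase, fell from 70.2 ± 14.8 to 43.1 ± 20.2 FPKM, 0 rose and 1 fell when adjusted over the list alone, PLIN4, FABP4 and CFD gave -0.19, 0.42 and 0.35, and the score differed by -0.048 (exact permutation test, adjusted p = 0.835). Of 3 nerve and Schwann cell genes, SCN7A fell from 8.39 ± 2.96 to 3.29 ± 1.05 FPKM, 0 rose and 1 fell when adjusted over the list alone, S100B gave 0.53, and the score differed by -0.14 (exact permutation test, adjusted p = 0.471). Of 13 housekeeping genes, GUSB rose from 14.6 ± 1.83 to 19.7 ± 2.97 FPKM, 1 rose and 0 fell when adjusted over the list alone, TBP and B2M gave -0.17 and 0.22, GAPDH gave 0.13, which turned to -0.050 with cores scaled to the same total without loci under 300 bp, and the score differed by 0.023 (exact permutation test, adjusted p = 0.778).

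In all, 17 of 37 list scores passed the exact permutation test after adjustment, 12 higher and 5 lower, and 20 had an unadjusted p under 0.05. Lower lists were 3, without type 2 and hypoxia, when any of control lungs 1 to 4 or IPF lungs 1, 2, 3, 4, 7, 8 and 10 was left out singly. With either set of controls alone all 17 kept their sign and 11 passed with both, without type 2, secretory, peribronchial, erythroid, platelet and hypoxia. The housekeeping score, at 0.023 (exact permutation test, adjusted p = 0.778) with all controls, differed by -0.14 (adjusted p = 0.0216) against controls with title numbers of up to 3 digits and 0.19 (adjusted p = 0.0162) against those with 4. The smallest p that the splits of 16 lungs can give is 0.000125. Camera with a preset correlation of 0.01 called 24 of 37 lists, against a median of 12 in 99 other splits of the lungs, and 0 calls held with an estimated correlation (10 at an unadjusted p under 0.05), where the lowest value was adjusted p = 0.0621 for the senescence list. With each core scaled to the same total, the limma comparison called 649 genes, 65.6% of them higher in IPF lungs, against 1808 and 53.5% as deposited, and with the 3 control lungs with title numbers of up to 3 digits alone it called 1377, 30.4% higher. Scaling to the same total without loci under 300 bp, an alternative chosen after the data were seen, gave 1914 genes, 28.4% higher, and moved the median of all genes to -0.17 on the log2 scale.

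Several cores per lung allowed the spread within a lung to be set beside that between lungs. Disease state held 10.0% of the sum of squares of an average gene, lungs of the same state held 43.4%, and cores of the same lung held 46.6%. By degrees of freedom alone these shares would be 1.21%, 16.9% and 81.9%. The median gene varied between the cores of a lung with an SD of 0.287 ± 0.051 log2 units in control and 0.282 ± 0.047 in IPF lungs (SD, n = 6 and 10), a difference of -0.0047 (exact permutation p = 0.855, two-sided, smallest possible p 0.000125).

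Single genes varied more from core to core in IPF lungs. By list, 3 of 14 metalloproteinase, 2 of 5 cartilage and bone, 2 of 17 B cell, 0 of 9 dendritic cell, 0 of 20 matrix and 0 of 12 smooth muscle genes passed, and 5, 3, 11, 6, 3 and 0 were more variable at an unadjusted p under 0.05. No test of spread was made per list. With the SD between cores as mean over lungs, control against IPF, those named were COL10A1 (0.104 against 0.782), the BMP antagonist GREM1 (0.153 against 0.674), and the metalloproteinases ADAMTS16 (0.0636 against 0.421) and ADAMTS14 (0.0948 against 0.415), along with BAAT (0.0588 against 0.464) and MED4-AS1 (0.291 against 1.05). Less variable in IPF were ABCC8 (0.524 against 0.123), SCARB1 (0.719 against 0.245), KCNMB4 (0.431 against 0.164) and the coagulation factor gene F8 (1.03 against 0.344). ALPP and ADRA1A, next by p, did not pass (limma adjusted p = 0.0656 and 0.101). Limma on the log2 SD called 54 of 14834 genes, 50 more and 4 less variable in IPF lungs (limma adjusted p from 5.69e-07 for BAAT to 0.0469 for F8 among those named). List members among the 50 also included MMP9, MMP11 and MMP13 of the metalloproteinases, CR2 and FCRL5 of the B cell list, and COL2A1, WT1 and KRT14, named after their values were seen. Most of these genes lay near the floor in control lungs (COL10A1 0.104 and GREM1 0.147 FPKM). With a pseudocount of 0.1, or with genes of mean FPKM of at least 5 alone, 1 gene was called, MED4-AS1, an antisense transcript. Without control lung 2 or 4, 35 or 34 genes were called.

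Within IPF lungs, the question was which genes go with the matrix score from core to core, with the lung as a block. The gelatinase gene MMP2 rose by 1.2 ± 0.072 log2 units (SE) per unit of matrix score over 49 cores. The other largest positive slopes were IGLL5 (1.43 ± 0.27), CST2 (1.19 ± 0.19), COL8A1 (1.16 ± 0.14), CTSE (1.14 ± 0.16), COL10A1 (1.14 ± 0.17), ISLR (1.12 ± 0.13), MFAP2 (1.11 ± 0.084), THBS2 (1.07 ± 0.11) and the mast cell tryptase gene TPSB2 (1.07 ± 0.18). The largest negative slope was that of the small RNA locus MIR5095 (-1.88 ± 0.68). Next came PSCA (-1.76 ± 0.50), SAA2 (-1.75 ± 0.45), SAA1 (-1.75 ± 0.45), SAA2-SAA4 (-1.65 ± 0.38), BPIFA1 (-1.65 ± 0.62), SERPINB3 (-1.53 ± 0.54) and C4orf22 (-1.49 ± 0.46), with the small RNA loci SNORD83B (-1.67 ± 0.62) and SNORD104 (-1.51 ± 0.57). The serum amyloid genes overlap and share sequence, and TPSB2 is near-identical to TPSAB1, so their single values are uncertain. Limma called 3599 of 14814 genes, 2296 positive and 1303 negative (limma adjusted p from 8.31e-16 for MMP2 to 0.0483 for SNORD104 among those named). None of 100 shuffles of the score within lungs called as many, with at most 62. Without IPF lung 3 or 10 the fit called 2392 or 2040 genes.

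Most pericyte and mast cell genes rose with the matrix score, as did some alveolar genes, and some airway genes fell. List members named here were chosen after their values were seen. Of 10 pericyte genes, 9 rose with the score, among them NDUFA4L2 (1.03 ± 0.12) and PDGFRB (0.68 ± 0.088), and the list score gave r = 0.80, permutation p = 1e-05, adjusted p = 0.00012, rho = 0.76, permutation p = 1e-05, r = 0.76 without the 2 cores farthest from the median matrix score, 10 of 10 lungs with that sign. Of 12 smooth muscle genes, 5 rose and 0 fell. Their score did not pass (r = 0.35, permutation p = 0.0438, adjusted p = 0.113, rho = 0.33, permutation p = 0.0441, r = 0.50 without the 2 cores farthest from the median matrix score, 6 of 10 lungs with that sign). Of 10 mast cell genes, 9 rose, among them TPSAB1 (1.03 ± 0.18) and the protease gene CPA3 (0.85 ± 0.17), and the list score gave r = 0.67, permutation p = 0.0001, adjusted p = 0.0009, rho = 0.55, permutation p = 0.00037, r = 0.57 without the 2 cores farthest from the median matrix score, 8 of 10 lungs with that sign. Of 18 genes of the transforming growth factor β pathway, 13 rose, among them LTBP2 (0.81 ± 0.094) and BMP4 (0.83 ± 0.11), and the score gave r = 0.74, permutation p = 2e-05, adjusted p = 0.000206, rho = 0.68, permutation p = 2e-05, r = 0.68 without the 2 cores farthest from the median matrix score, 9 of 10 lungs with that sign. Of 14 type 2 genes, 7 rose and 0 fell, among them the surfactant genes SFTPC (0.65 ± 0.21) and SFTPD (0.81 ± 0.21), and the score gave r = 0.44, permutation p = 0.00806, adjusted p = 0.0341, rho = 0.32, permutation p = 0.0355, r = 0.33 without the 2 cores farthest from the median matrix score, 7 of 10 lungs with that sign. Of 13 type 1 genes, 6 rose and 0 fell, among them HOPX (0.66 ± 0.12) and AQP4 (0.70 ± 0.23). The type 1 score did not pass (r = 0.32, permutation p = 0.0507, adjusted p = 0.126, rho = 0.18, permutation p = 0.261, r = 0.18 without the 2 cores farthest from the median matrix score, 7 of 10 lungs with that sign). Of 16 ciliated genes, 9 fell and 0 rose, among them FOXJ1 (-1.01 ± 0.38) and RSPH1 (-1.34 ± 0.45), and the score gave r = -0.38, permutation p = 0.00784, adjusted p = 0.0341, rho = -0.35, permutation p = 0.0234, r = -0.26 without the 2 cores farthest from the median matrix score, 6 of 10 lungs with that sign. Of 16 secretory genes, 6 fell and 0 rose, among them MUC5B (-0.97 ± 0.33) and TFF3 (-1.32 ± 0.42). The secretory score did not pass (r = -0.36, permutation p = 0.0165, adjusted p = 0.0625, rho = -0.32, permutation p = 0.0458, r = -0.22 without the 2 cores farthest from the median matrix score, 7 of 10 lungs with that sign).

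Other list scores that passed in IPF cores by permutation within lungs were, each with r, adjusted permutation p and rho, metalloproteinases (r = 0.66, adjusted p = 0.00012, rho = 0.71), senescence (r = 0.70, adjusted p = 0.00012, rho = 0.67), Wnt (r = 0.75, adjusted p = 0.00012, rho = 0.72), cartilage and bone (r = 0.68, adjusted p = 0.00012, rho = 0.75), dendritic cell (r = 0.65, adjusted p = 0.00192, rho = 0.49), follicle chemokine (r = 0.53, adjusted p = 0.0116, rho = 0.49), proliferation (r = 0.43, adjusted p = 0.0242, rho = 0.39), unfolded protein response (r = 0.42, adjusted p = 0.0284, rho = 0.29) and SPP1 macrophage (r = 0.50, adjusted p = 0.0322, rho = 0.38). Of 72 relations computed, 36 per disease state, 14 passed in IPF cores, 13 positive and 1 negative, and 3 in control cores, all positive. The housekeeping score did not pass in IPF cores but also leaned upward (r = 0.35, permutation p = 0.0287, adjusted p = 0.0831, rho = 0.18, permutation p = 0.241). The smallest p that 100000 permutations can give is 1e-05. The controls' 3 were smooth muscle (r = 0.75, adjusted p = 0.00012, rho = 0.71), metalloproteinase (r = 0.55, adjusted p = 0.0238, rho = 0.59) and peribronchial endothelial scores (r = 0.56, adjusted p = 0.0242, rho = 0.46). Removing the 2 cores farthest from the median matrix score weakened the ciliated, type 2, SPP1 macrophage and dendritic cell relations to r = -0.26, 0.33, 0.26 and 0.50, and that of metalloproteinases in control cores to 0.36. By rho, ciliated, type 2, SPP1 macrophage, proliferation and unfolded protein response scores missed the threshold, as did the peribronchial score in control cores.

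**Figure D4:**
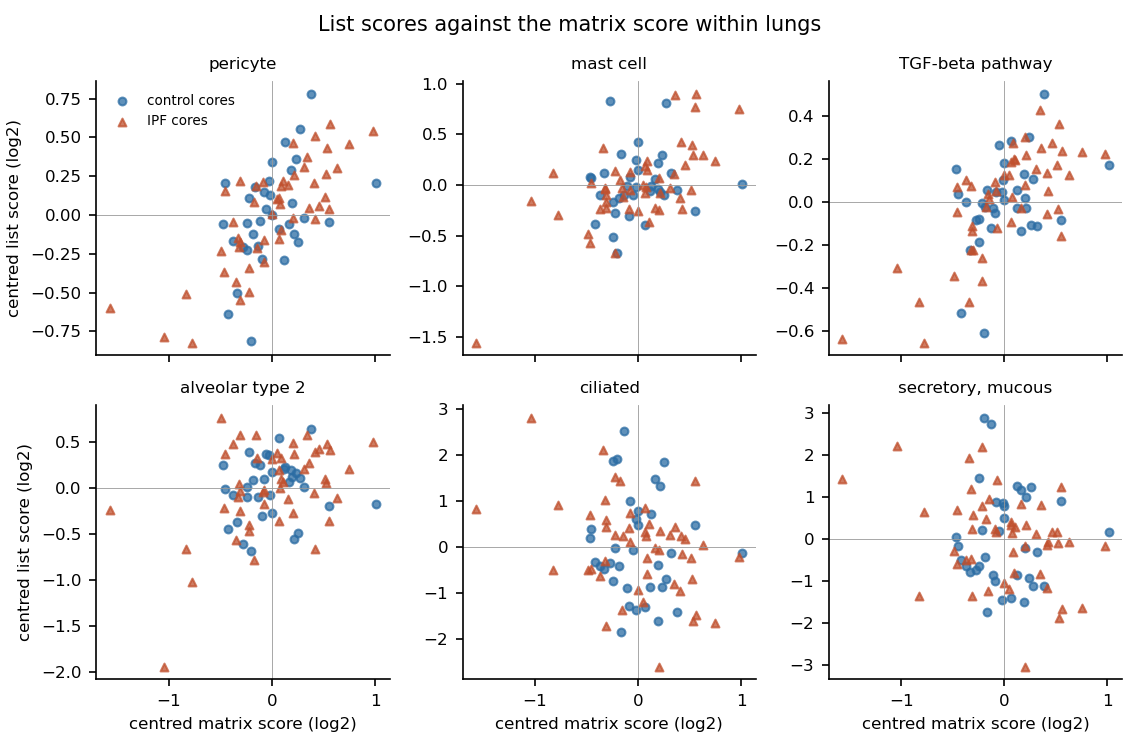
Centred list scores (vertical axes, log2 units after subtraction of the lung mean) against the centred matrix score (horizontal axis) for 6 lists, with IPF cores as red triangles (49) and control cores as blue circles (35). Pericyte (r = 0.80) and mast cell scores (r = 0.67) rose with the matrix score in IPF cores, and the ciliated score fell (r = -0.38).

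In control lungs the same fit called 126 genes, 125 positive and 1 negative (HIST1H2BE, -1.32 ± 0.33), and 1480 at an unadjusted p under 0.05. Of 12 smooth muscle genes, 6 rose with the score and 0 fell, against 5 and 0 in IPF cores. Genes called included ACTG2 (2.07 ± 0.38), CNN1 (1.70 ± 0.28) and TAGLN (1.70 ± 0.26) of that list, beside PLA2G2A (2.93 ± 0.74), SMOC2 (1.72 ± 0.24) and PTGIS (1.69 ± 0.28). These were named after their values were seen. Of 100 shuffles of the score within control lungs, 2 called as many genes, with at most 516, and without control lung 1, 3 or 6 the fit called 0, 60 or 83 genes. The matrix score varied less between cores in control (SD 0.332) than in IPF lungs (0.533). None of 36 differences in r between disease states passed after adjustment (permutation of disease state over lungs), and 6 had an unadjusted p under 0.05.

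Genes that differed between IPF and control lungs and genes that went with the matrix score within IPF lungs overlapped in part. Of 950 tested genes higher in IPF lungs, 364 rose with the matrix score, where independent lists would share 147.2, and 35 fell, against 83.6 expected. Of 841 genes lower in IPF lungs, 98 fell with the matrix score, against 74.0 expected, and 44 rose, against 130.3 expected. The remaining 551 higher and 699 lower genes showed no relation past the threshold. No test of these overlaps was made. They were also not recomputed with the share of short loci as a covariate, where the fit called 559 genes in place of 3599. A technical part of the overlap therefore stays open.

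The share of short loci moved with the matrix score. Within IPF lungs it fell as the score rose (r = -0.67, permutation p = 1e-05, adjusted p = 4e-05 over 4 technical relations, rho = -0.70, permutation p = 1e-05, r = -0.62 without the 2 cores farthest from the median share). In control lungs r was -0.40 (permutation p = 0.0516, adjusted p = 0.103, rho = -0.31, permutation p = 0.0964). Of 98 small nucleolar RNA genes, a family chosen after its values were seen, 62 fell with the matrix score in IPF cores and 0 rose. With short-locus share as a covariate, chosen after the data were seen, the fit in IPF cores called 559 genes, 448 positive and 111 negative. Of the 20 named slopes, 10 no longer passed. With that share removed within lungs, 10 list relations passed in place of 17 over both disease states, and 7 of the 17 were lost. The type 2 correlation in IPF cores went from 0.440 to 0.123. Scaling each core to the same total gave 12143 genes, 12023 of them positive, and with the type 1 score, sign turned, in place of the matrix score, 18 of the 20 named slopes changed sign.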

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

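Of the tests below, those chosen before their values were seen were the neutrophil and platelet difference with short-locus share as a covariate, the airway values after removal of short-locus share and of depth, and the share of calls kept with either set of controls; all other tests, the splits of lungs included, were chosen after the results were seen. A lung far from the others of its state was found in 7 of 134 groups tested, and chance alone gives about 1 in 20 (5%), or 6.7. In control lungs, 1 lung lay above the rest for the SPP1 macrophage score (6.095, next 5.359), the unfolded protein response score (5.437, next 4.768), IGLL5 (9.233, next 6.26) and COMP (3.838, next 1.857), the 2 scores in the same lung and each gene taken by itself. MT1M was lowest in 1 control lung (5.175, next 8.019). In IPF lungs, 1 lung lay above the rest for DEFA3 (2.836, next 1.363) and DEFA1 (2.484, next 1.349). All are log2(FPKM + 1), and none was weighed further.

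Neutrophil and platelet scores fell in IPF lungs while the erythroid score rose. Past the limma threshold, 9 of 15 neutrophil and 7 of 8 platelet genes fell, and 3 of 7 erythroid genes, all globins, rose. Less blood left in the IPF cores would lower all 3 lists, whereas the erythroid difference was 1.523 (SE 0.552). It was 2.31 (SE 0.433) with controls of up to 3 digits and 0.735 (SE 0.651) with the others. Less blood alone would not give that rise. The rise is itself part of the pattern and rests on globin genes, so it was no separate test, and a part played by blood content stays open. With short-locus share as a covariate, the mean of the neutrophil and platelet differences was -1.382 against -1.43 without it. It lay between -1.8 and -1.24 when single lungs were left out, which argued against a linear effect of that share as the cause. Acute inflammation of control lungs before sampling may have raised neutrophil genes there, and it stayed open, since the difference of the acute inflammation score (0.2065, SE 0.284) was too imprecise to decide. A loss of marginated neutrophils and platelets with the capillary bed may also account for the fall, and it was not tested.

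Within IPF lungs, pericyte, mast cell and type 2 scores rose with the matrix score and the ciliated score fell. The other airway score, secretory, fell without passing (r = -0.36, permutation within lungs, adjusted p = 0.0625). A varying share of airway epithelium could produce this pattern, yet with airway scores removed the mean r of the pericyte and mast cell scores stayed at 0.7342 (0.734 before), while the alveolar r went from 0.440 to 0.2818 and stays open. With short-locus share removed, the mean r of pericyte and mast cell scores was 0.662 (0.543 to 0.717 with single lungs left out), which argued against that share as the whole cause, but the alveolar r dropped to 0.1225 (0.0196 to 0.180), as that explanation requires, and the airway r of -0.1659 (-0.370 before, -0.264 to -0.119) left that part open. Removal of read depth left 0.7224, 0.4021 and -0.3634, against depth as the cause of any of the 3 parts. The rise of pericyte and mast cell genes with matrix genes (the smooth muscle score, r = 0.35, adjusted p = 0.113, did not pass) may be biological, as a hypothesis found and tested on the same cores. A general upward drift of values with the matrix score was not tested and stays open. The housekeeping score also leaned upward in IPF cores (r = 0.35, permutation p = 0.0287, adjusted p = 0.0831). The alveolar rise may be technical.

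The 3 control lungs with 4-digit title numbers had short-locus shares of 80.5% to 91.1%, and the other 3 had 69.7% to 74.5%. Of the 1808 disease calls, 76.55% (1384) kept their sign and an unadjusted p under 0.05 with either set of controls (69.6% to 81.9% with single lungs left out) and 463 were called with both, but the genes were chosen as called and both comparisons share the IPF lungs, so whether one set could carry most calls stays open. With short-locus share as a covariate, 97.73% (1767) were called (79.2% to 100% with single lungs left out), against a linear effect of that share as their source. The genes were again chosen as called, and the share differed little between states (79.7% in control and 76.8% in IPF lungs). Scaling each core to the same total kept 626 of the 1808 calls, so other effects of that share stay open. A sampling or library batch that goes with the title style could lie behind the shares, and the exact permutation p of 0.1, the smallest that 20 splits allow, cannot decide it. All IPF lungs have title numbers of up to 3 digits, so such a batch cannot be told apart from disease in a comparison with the 4-digit controls alone.

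Other splits of the 16 lungs into 6 and 10 were drawn, 100 with the real one. Only the real split, 1 of 100, gave as many disease calls (1808), which argued against chance as the source of the count but says nothing about single genes. The highest count of another split was 1334. That other split had the largest difference in short-locus share of all, -7.53 points, and the next gave 41 genes. For the camera lists, 4 of 100 splits gave as many as the 24 called (highest other 25, median of the others 12). A list call by itself therefore says little. The 100 splits are a sample of all possible ones, so a share this close to 0.05 cannot decide whether chance is excluded. Camera also gave 0 lists with an estimated correlation. For spread per gene, only the real split, 1 of 100, gave as many calls (54, highest other 13), which argued against chance as the source of the count. Other splits also remove the difference in level between states. They therefore cannot tell greater spread from genes that leave the floor in IPF lungs. With a pseudocount of 0.1, 1 gene was called.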

How the results depend on the processing

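None of the 1808 disease calls changed sign in an alternative that tested it, and single lungs left out gave 1265 to 2016 calls, with 1065 genes called in all 16 fits. Of 110 named genes that passed for disease, 45 no longer passed with controls of up to 3 digits alone and 32 with 4-digit controls alone. With cores scaled to the same total, 40 no longer passed. Counts outside 1.5 times the original were 1047 with a mean of at least 5 FPKM (fewer genes tested), 649 with cores scaled to the same total and 6739 with lungs ignored, which counts cores as independent. Counts with the nlme model, duplicateCorrelation and short-locus share as a covariate were 1612, 2446 and 2483, and with controls of up to 3 or of 4 digits alone 1377 and 1817 (60.4% higher). The 17 list scores became 13 to 18 with single lungs left out, and the 5 lower ones became 3 in 11 of 16 such fits (type 2 and hypoxia passed in 4 each). Camera gave 0 lists with an estimated correlation. Signs turned, with no difference past the threshold, for CNN1 (-0.033) with 4-digit controls, for B2M (-0.34), GAPDH (-0.047), HSPH1 (-0.062), OAS1 (-0.12), OAS2 (-0.043), OAS3 (-0.029) and PLIN4 (0.16) with the other controls, and for GAPDH (-0.050) with the same total without short loci. Score differences turned with controls of up to 3 digits for heat shock (-0.12), housekeeping (-0.14, adjusted p = 0.0216), interferon (-0.23), lymphatic (-0.35), mesothelium (-0.29) and pericyte (-0.015), and with 4-digit controls for smooth muscle (-0.025) and unfolded protein response (0.084). They turned for adipocyte (0.072) and mesothelium (-0.0092) with the same total, mesothelium with a pseudocount of 5 (-0.046), and lymphatic without shallow cores (-0.012) and by z scores (-0.20). Single lungs left out gave ranges across 0 for adipocyte (-0.12 to 0.053), housekeeping (-0.022 to 0.066), lymphatic (-0.16 to 0.15), mesothelium (-0.099 to 0.12), pericyte (-0.015 to 0.17) and unfolded protein response (-0.19 to 0.023). The difference in median spread was 0.0014 with quantile normalization, 0.0021 with 4 cores per lung, and -0.015 to 0.014 with single lungs left out. Genes called for spread fell from 54 to 1 with a pseudocount of 0.1 and 1 with a mean of at least 5 FPKM, and were 34 to 73 with single lungs left out (35 and 34 without control lungs 2 and 4). The 3599 genes related to the matrix score became 2173 with a mean of at least 5 FPKM, 12143 with the same total, 7135 with the type 1 score, 1380 with 3 collagens, 1493 with ranks, 559 with short-locus share as a covariate and 2290 without shallow cores. Single lungs left out gave 2040 to 4314 (2392 without IPF lung 3, 2040 without lung 10), and in controls 0 to 180 (0, 60 and 83 without control lungs 1, 3 and 6). Of the 20 named slopes, 10 no longer passed with short-locus share as a covariate, 7 with ranks and 7 without IPF lung 3. With the type 1 score, slopes turned to BPIFA1 3.05, C4orf22 2.83, COL10A1 -0.92, COL8A1 -1.39, CST2 -1.18, CTSE -1.14, ISLR -0.19, MFAP2 -0.49, MMP2 -0.39, PSCA 2.81, SAA1 2.22, SAA2 2.31, SAA2-SAA4 1.87, SERPINB3 2.23, SNORD104 0.76, SNORD83B 1.01, THBS2 -0.21 and TPSB2 -0.39. The 17 list correlations became 10 with short-locus share removed and 13 to 19 with single lungs left out, and in controls signs turned for unfolded protein response (-0.053 with that share removed), type 2 (-0.12 to 0.20), ciliated (-0.13 to 0.12) and proliferation (-0.061 to 0.23). Apart from the fewer genes tested, the cause was not tested. Read depth is known only relative to the median core, so what it limits could not be given in reads.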

Other observations

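The families below were chosen after their values were seen. Metallothionein genes, which bind zinc and copper and respond to metals and glucocorticoids, fell in IPF lungs in 5 of 11 measured (MT1A, MT1JP, MT1L, MT1M and MT2A, limma with Benjamini-Hochberg), and 0 rose. MT2A fell from 5698 ± 2931 to 2055 ± 1394 FPKM and MT1L fell from 150.2 ± 61.4 to 47.4 ± 11.8 FPKM, both in 10 of 10 IPF lungs relative to the control mean. MT1F went the other way without passing (54.5 ± 20.1 against 75 ± 22.5 FPKM, adjusted p = 0.0892). These genes share sequence, so single values are uncertain. All 3 alpha-defensin genes measured fell, DEFA4 from 11.8 ± 13.1 to 0.763 ± 1.24 FPKM, and within IPF lungs DEFA4 also fell with the matrix score (slope -0.81 ± 0.17, adjusted p = 0.000606).

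Of 30 collagen genes, 15 rose and 0 fell. Beyond fibrillar collagens these included COL17A1, the hemidesmosome collagen of basal epithelium, from 0.251 ± 0.164 to 3.29 ± 2.39 FPKM, and COL16A1, from 6.26 ± 1.31 to 21.7 ± 9.57 FPKM. Of the basement membrane zone, COL18A1, COL15A1 and COL7A1 rose by 0.95, 1.69 and 0.63 on the log2 scale, and none of 5 type IV genes passed, among them COL4A1 (32.5 ± 10.4 against 57 ± 30.6 FPKM, adjusted p = 0.191) and COL4A3 (adjusted p = 0.84). Of 15 keratin genes, 6 rose (KRT5, KRT8, KRT14, KRT15, KRT16 and KRT17) and 0 fell. KRT8 rose from 92.2 ± 25.3 to 173 ± 67.7 FPKM, and KRT18, its partner in simple epithelium, stood at 141 ± 55.8 against 139 ± 26.2 FPKM (adjusted p = 0.776).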
